A study of Arabidopsis thaliana with 26 samples.

How the data were processed

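Transcript levels were measured with the Affymetrix ATH1 array in leaves of Arabidopsis thaliana, accession Col-0, grown under ambient CO2 and ambient light in a 10 h light period. Developing leaves were sampled at 2, 4, 12, 24, 48 and 96 h with 4 arrays at each time, and mature leaves at 24 h with 2 arrays, 26 arrays in all. The labels number the replicates but do not say whether each came from a separate plant, so the p-values measure the spread between these samples only. They do not give the clock time from which the hours were counted.

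The deposited table held 1 intensity per probe set and array, made by the authors with MAS5. The values were on a linear scale and every array had been scaled to the same trimmed mean, which leaves out the lowest and highest 2% of probe sets. No detection calls came with the table, and the version of MAS5, the background correction and the scaling settings were not stated. The authors' scaling was kept.

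The table held 22810 probe sets, of which 64 AFFX controls were left out of the tests. Each value was taken as log2 of the intensity plus a pseudocount of 4.35, which is 10% of the median of all values. Probe sets whose mean log2 value over the 26 arrays lay under the 40th percentile were left out, since no detection calls were available, which left 13648. Of these, 7445 named 1 gene in the platform annotation, 259 named several and 5944 named none, so the counts cover probe sets and the named genes cover the annotated part only. The number of arrays limits the precision, and there is no count of molecules behind an array value.

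All tests across probe sets used limma 3.58.1 in R 4.3.3. The 7 groups entered 1 fit, with an intensity trend in the variance prior, and Benjamini-Hochberg adjustment ran over the 13648 probe sets of each comparison with a threshold of 0.05. The times in developing leaves were compared by a moderated F-test over the 6 times and by contrasts of each later time against 2 h, of 48 h and 96 h against 24 h, and mature leaves were compared with developing leaves at 24 h. With 2 mature arrays, the spread in that comparison came mostly from the developing groups. Arrays of mature leaves (mean r 0.969) and of developing leaves at 24 h (0.967) correlated less within their group than those of other groups (0.978 to 0.981). The shared spread may thus be too small for comparisons that hold these groups, and their p-values too low. Fold changes are log2 values with the standard error (SE) of the fit, and levels are means with the standard deviation (SD) between arrays.

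Before the data were examined, 24 pathway lists and 6 lists of markers for other cell types and organs were fixed, with the tests, the filter, the named-gene rule and most alternatives. The platform annotation paired few of their genes with a probe set, and the filter removed some of those. As a result, 21 of these 30 lists had fewer than 3 measured members and were not tested as lists. For senescence and chlorophyll breakdown 3 genes had a probe set but 0 passed the filter, and for auxin response 4 had one and 2 passed. A further 37 lists were then written from the annotation. This was done after summaries of whole arrays had been seen but before any test of a gene, and 3 of them were too small to test. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 72 tests of the fixed lists and over the 272 tests of the added lists. The same test with an estimated correlation gave no list under the threshold, and its adjusted p stands beside each list that passed with the preset one. A list holds each gene once, and the added lists share members with the fixed ones.

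The named-gene rule took the 12 largest rises and the 12 largest falls in the comparison of mature with developing leaves, and the 8 largest of each in every time comparison. They had to pass the threshold, to name 1 gene and to have values that did not overlap between the groups. For the F-test it took the 10 probe sets with the smallest p. These named no gene, so the 10 with the smallest p among those that named 1 were taken instead. It added up to 4 members of each list that passed and the measured clock genes. Members of lists that did not pass are named because the lists were fixed, or are marked as chosen later.

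RNA quality was measured as the log2 ratio of the 3 prime to the 5 prime control probe sets for GAPDH, actin and ubiquitin on each array. Groups were compared with 2-sided exact permutation tests, 24 in all, for which the smallest possible p is 0.0286 with 4 arrays against 4 and 0.0667 with 2 against 4. An adjusted p under 0.05 would need many of the 24 tests at the smallest p at once. A high adjusted p therefore does not show that the ratios were alike.

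The fit was tested on simulated data with the real mean and spread of each probe set. The probe sets were drawn independently of each other and without an effect of the replicate number. The simulation therefore does not cover correlated genes. Changes of 1 on the log2 scale were recovered in 89.6% of cases for 96 h against 24 h and in 92.5% for mature against developing leaves, and changes of 0.5 in 49.3% and 28.4%. False calls made up 3.64% and 4.55% of the calls. For the F-test, changes of 1 in a single group were recovered in 97.0% of cases, and 5.03% of the calls were false. A simulated list shifted by 0.5 passed camera, and so did 1 of the unshifted lists.

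The alternatives were quantile normalization, a pseudocount of 21.7 or none, a filter at the 60th percentile or none, a fit to the arrays of the compared groups only, the replicate number as a block, a variance prior without the trend, and leaving out each array of the compared groups in turn. Another 4 were chosen after seeing the data. These were developing 24 h replicate 1 out of the fit, limma's array weights, and the actin or the ubiquitin ratio as a covariate. Other treatments, implied by the title of the study, were not part of the deposited series and were not analysed.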

Results

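The series followed leaves of Arabidopsis kept under ambient CO2 and ambient light, the first treatment of a study on systemic signalling of irradiance and CO2. Developing leaves, from leaf insertions 19 to 21, gave 4 arrays at each of 2, 4, 12, 24, 48 and 96 h, and mature leaves gave 2 arrays at 24 h. The median intensity of an array lay between 40.7 and 47.0, and arrays of the same group correlated with a mean r of 0.967 to 0.981 across probe sets, which are not independent replicates. Under 1 treatment, the time comparisons show how transcript levels moved over hours and over 4 days, and the last comparison shows how mature leaves differed from developing ones.

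Most measured transcripts in developing leaves differed among the 6 times. The named genes with the smallest p included CCL, with a mean log2 level of 8.22 ± 0.42 (SD, n = 4) at 2 h, 10.78 ± 0.07 at 12 h and 6.54 ± 0.35 at 24 h. AT1G56300 stood at 8.43 ± 0.15 at 4 h and at 4.29 ± 0.25 at 24 h. AT3G09440, a gene for a heat shock protein of the HSP70 family, moved the other way, from 8.17 ± 0.23 at 12 h to 11.17 ± 0.19 at 24 h. Low points at 12 h were also measured for AT3G01060 (6.05 ± 0.16), AT3G21670 (5.12 ± 0.43), AT5G12110 (5.51 ± 0.24), AT5G35970 (5.69 ± 0.13), the beta-glucosidase gene BGLU40 (6.61 ± 0.11) and the cytochrome P450 gene CYP71B26 (4.78 ± 0.12). AT4G32340 was at 8.09 ± 0.16 at 12 h against 4.48 ± 0.40 at 24 h. GI, a component of the circadian clock, was at 5.89 ± 0.10 at 2 h, 7.41 ± 0.10 at 4 h, 3.69 ± 0.49 at 12 h and 5.72 ± 0.26 at 24 h. AT5G52660, the only measured gene of the morning clock list, stayed between 5.63 ± 0.10 and 6.02 ± 0.18 and passed in no time comparison. By the moderated F-test, 8515 of 13648 probe sets (62.4%) differed among the times. The level of AT5G12110 was set apart by 1 array at 24 h and by another at 96 h.

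**Figure D1:**
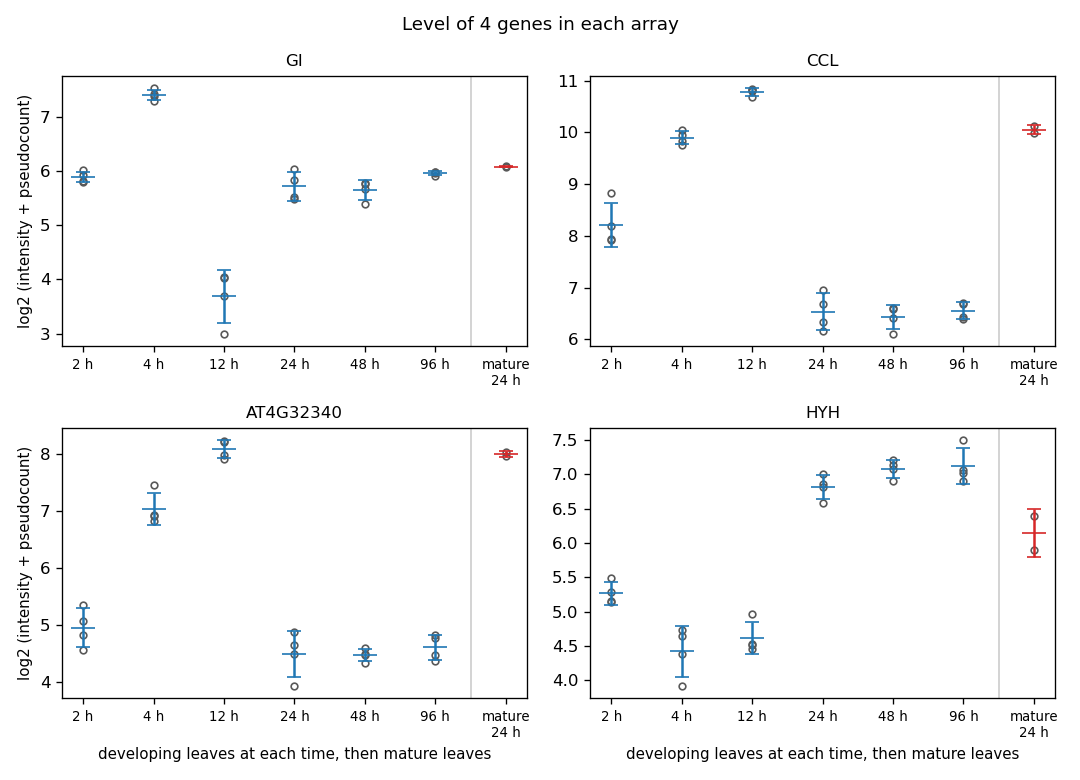
Log2 intensity plus pseudocount of GI, CCL, AT4G32340 and HYH in each array (circles), with the group mean and SD (bars), for developing leaves at 6 times (blue) and mature leaves at 24 h (red). GI was at 7.41 at 4 h and at 3.69 at 12 h, and CCL was at 10.78 at 12 h and at 6.54 at 24 h.

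Between 2 h and 4 h the largest rise among named genes was that of AT1G56300, 5.79-fold (log2 2.53 ± 0.19 SE, 4 arrays against 4). AT4G32340 rose by 2.08 ± 0.18, AT4G16146 by 1.78 ± 0.15, CCL by 1.68 ± 0.16 and GI by 1.52 ± 0.16. AT3G62550 rose by 1.44 ± 0.18, AT2G21130 by 1.38 ± 0.15 and COR15B, a cold-regulated gene, by 1.43 ± 0.19. The largest falls among named genes were those of AT1G65490 (-1.17 ± 0.21) and of MGL, which codes for methionine gamma-lyase (-1.09 ± 0.17). Falls followed in AT4G24700 (-0.92 ± 0.16), HYH, a transcription factor of light signalling (-0.85 ± 0.16), AT5G62130 (-0.82 ± 0.18), AT2G40435 (-0.82 ± 0.14), the glutathione reductase gene GR1 (-0.81 ± 0.13) and AT5G19240 (-0.78 ± 0.14). In all, 319 of 13648 probe sets passed, 183 up and 136 down, and 28 and 12 of these changed at least 2-fold. With array weights 567 passed, and AT5G62130 did not pass without developing 4 h replicate 4 (adjusted p = 0.0680).

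Genes of mitosis and cytokinesis rose as a list from 2 h to 4 h, with a median log2 fold of 0.30. Of 17 measured members 5 rose, among them KINESIN-12B (0.74 ± 0.16), the topoisomerase gene TOPII (0.74 ± 0.18), 3xHMG-box2 (0.68 ± 0.15) and the Aurora kinase gene AUR1 (0.45 ± 0.11). The list had an adjusted p of 1.55e-07 in camera, and an adjusted p of 0.103 with an estimated correlation. Of 11 genes of chlorophyll and haem synthesis 2 rose, PORB, a protochlorophyllide reductase (1.12 ± 0.14), and CHLI2, a subunit of magnesium chelatase (0.47 ± 0.10). That list had an adjusted p of 4.90e-05, and an adjusted p of 0.141 with an estimated correlation. Of 9 genes of cold and dehydration response, COR15B alone rose, and COR15A was at 0.86 ± 0.31 with an adjusted p of 0.199. The list's adjusted p was 0.0135, with an adjusted p of 0.198 with an estimated correlation and 0.0612 without the filter. Among 7 expansin genes EXPB1 fell (-0.73 ± 0.17), with an adjusted p of 0.0497 for the list and an adjusted p of 0.190 with an estimated correlation. The expansin call was lost under 6 other settings and without any 1 of 5 arrays, developing 2 h replicates 1, 3 and 4 and developing 4 h replicates 1 and 2, where the adjusted p was 0.0718, 0.0805, 0.115, 0.140 and 0.0797. Histones, replication genes and ribosomal proteins also passed as lists with no member called. Their median folds were 0.17 in 11 core and linker histones (adjusted p = 0.00485, adjusted p = 0.285 with an estimated correlation), -0.22 in 12 genes of replication and chromatin assembly (0.00247, adjusted p = 0.351 with an estimated correlation) and 0.11 in 119 cytosolic ribosomal proteins (3.31e-08, adjusted p = 0.447 with an estimated correlation). Under quantile normalization the medians of the histones and the ribosomal proteins were 0.11 and 0.02 and neither list passed. Among the genes named here, AUR1, TOPII, CHLI2, EXPB1 and 3xHMG-box2 did not pass without 5, 5, 3, 3 and 1 of the 8 arrays left out in turn, with an adjusted p of up to 0.159, 0.0948, 0.0651, 0.0579 and 0.0546, and AUR1 (0.0510) and CHLI2 (0.0507) did not pass with the arrays of these groups only. Of the fixed lists measured by 2 genes, both for starch breakdown rose, DPE1 by 0.70 and PWD by 0.62.

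At 12 h, AT3G60420 stood 13.7-fold above its level at 2 h (log2 3.77 ± 0.43 SE, 4 arrays against 4) and AT4G32340 8.79-fold (3.14 ± 0.18). The lectin gene AT3G16530 rose by 2.62 ± 0.40, AT1G25275 by 2.60 ± 0.17, AT3G15630 by 2.57 ± 0.16, CCL by 2.56 ± 0.16, AT3G62550 by 2.44 ± 0.18 and AT4G38550 by 2.2 ± 0.13. Among named genes the largest falls were those of AT1G13650 (-3.92 ± 0.21), AT3G21670 (-3.36 ± 0.15) and CYP71B26 (-3.06 ± 0.13). Further falls were those of AT3G28220 (-2.73 ± 0.23), AT2G20670 (-2.52 ± 0.22), the thionin gene THI2.2 (-2.42 ± 0.30), the methionine sulfoxide reductase gene MSRB6 (-2.35 ± 0.18) and AT1G76240 (-2.25 ± 0.10). GI fell as well (-2.2 ± 0.16). AT1G13650 and AT2G20670 were near the floor at 12 h (3.2 ± 0.31 and 2.89 ± 0.39, SD, n = 4), where the pseudocount sets the size of a fold. Of 13648 probe sets 5353 passed, 2811 up and 2542 down, and at least 2-fold changes numbered 294 up and 479 down.

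Cytosolic ribosomal proteins, histones and replication genes were lower at 12 h than at 2 h. Of 119 ribosomal protein genes 55 fell and none rose, with a median log2 fold of -0.21. AT3G16780 was at -1.17 ± 0.09 and AT2G32220 at -1.37 ± 0.12 (list adjusted p = 8.84e-09, adjusted p = 0.418 with an estimated correlation). Of 11 histones 7 fell and 1 rose, with AT2G37470 at -1.39 ± 0.14 and the histone H2B gene HTB11 at -0.97 ± 0.10 (list adjusted p = 0.00994, adjusted p = 0.329 with an estimated correlation). Of 12 genes of replication and chromatin assembly 8 fell, among them the DNA polymerase alpha subunit POLA3 (-1.23 ± 0.11), the replicative helicase subunit PRL (-1.10 ± 0.11) and CHR17 (-0.98 ± 0.13). FAC1, which codes for an AMP deaminase and not for a replication protein, is a member of that list and fell by 0.62 ± 0.09 (list adjusted p = 1.46e-04, adjusted p = 0.244 with an estimated correlation). Of 14 serine carboxypeptidase-like genes 5 rose, with SCPL49 at 2.06 ± 0.13 and scpl35 at 1.79 ± 0.11 (list adjusted p = 0.0455, adjusted p = 0.231 with an estimated correlation). That last call was lost under 5 other settings, with the replicate block among them (adjusted p = 0.0505), and without developing 2 h replicate 1 (0.0746) or developing 12 h replicate 1 (0.0657). The actin control ratio was 2.66 ± 0.15 (SD, n = 4) at 2 h and 2.09 ± 0.37 at 12 h (exact permutation p = 0.0571) and the GAPDH ratio 0.31 ± 0.13 and 0.56 ± 0.21 (exact permutation p = 0.0857), both 0.229 adjusted over 24 tests, and 4766 probe sets passed with the actin ratio as a covariate. Among the fixed lists, none of which passed, 3 of 4 carbon starvation genes rose (3 adjusted over the list alone), and all 3 measured glucosinolate synthesis genes fell (3 adjusted over the list alone).

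At 24 h against 2 h, AT5G48570, a gene of the heat shock list, rose 5.50-fold (log2 2.46 ± 0.23 SE, 4 arrays against 4). AT5G12110 rose by 1.90 ± 0.17, AT3G56290 by 1.75 ± 0.16, AT3G16530 by 1.63 ± 0.40, AT1G68440 by 1.59 ± 0.32, HYH by 1.55 ± 0.16, AT3G28270 by 1.5 ± 0.34 and MGL by 1.43 ± 0.17. The pyruvate decarboxylase gene PDC2 fell 4.29-fold (-2.10 ± 0.28). AT1G70820 (-1.74 ± 0.15), AT3G51660 (-1.73 ± 0.17), AT5G27280 (-1.71 ± 0.38), the histone gene AT2G28720 (-1.70 ± 0.23), CCL (-1.68 ± 0.16), AT5G08520 (-1.67 ± 0.40) and AT1G56300 (-1.60 ± 0.19) also fell. GI was at -0.17 ± 0.16 and did not pass. The threshold was passed by 2856 probe sets, 1384 up and 1472 down, with 77 in each direction at 2-fold or more.

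Nuclear photosynthesis genes were higher at 24 h than at 2 h, with 15 of 22 up and 1 down and a median log2 fold of 0.42. The Rubisco activase gene RCA rose by 0.70 ± 0.15, the Calvin cycle enzyme gene SBPASE by 0.59 ± 0.11 and PSAN, a photosystem I subunit, by 0.58 ± 0.11. LHCB4.1, a light-harvesting protein, was at 0.59 ± 0.12, but at -0.03 under quantile normalization. The list had an adjusted p of 3.63e-06, and an adjusted p of 0.352 with an estimated correlation. Its median was 0.27 without developing 24 h replicate 1 and 0.15 under quantile normalization, and it passed in both. Of these 22 genes 10 also belonged to fixed lists, which did not pass. All 4 photosystem subunits rose (4 adjusted over the list alone, list adjusted p = 0.0603), as did 3 of 4 Calvin cycle enzymes (3, 0.0603) and all 3 light-harvesting proteins (3, 0.0820). Of 11 histones 7 fell and 1 rose, with HTB11 at -1.04 ± 0.10 and the linker histone gene AT1G06760 at -0.70 ± 0.09 (list adjusted p = 1.05e-06, adjusted p = 0.141 with an estimated correlation). Of 17 genes of mitosis and cytokinesis 5 fell, with 3xHMG-box2 at -0.79 ± 0.15 and the spindle checkpoint gene BUB3.1 at -0.61 ± 0.12. The mitosis list had an adjusted p of 0.00546, an adjusted p of 0.244 with an estimated correlation, and 0.0561 with the filter at the 60th percentile. Of 12 replication genes 4 fell, namely CHR17 (-0.50 ± 0.13), ASF1B (-0.47 ± 0.14), RECQ4A (-0.88 ± 0.29) and PSF2 (-0.38 ± 0.13). The replication list had an adjusted p of 0.0190 and an adjusted p of 0.450 with an estimated correlation. Its call was lost without developing 24 h replicate 1 (adjusted p = 0.0797), with array weights (0.0655) and with the filter at the 60th percentile (0.221). RECQ4A, PSF2 and ASF1B did not pass without 4, 4 and 2 of the 8 arrays left out in turn, with an adjusted p of up to 0.133, 0.165 and 0.0721, and RECQ4A (0.0610) and PSF2 (0.0657) did not pass without the filter, nor PSF2 with the actin ratio as a covariate (0.123). The actin control ratio was 2.66 ± 0.15 (SD, n = 4) at 2 h and 2.14 ± 0.49 at 24 h (exact permutation p = 0.0857, 0.229 adjusted over 24 tests), and 2301 probe sets passed with it as a covariate.

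After 48 h, the largest rise over 2 h among named genes was that of TBL26, 4.60-fold (log2 2.2 ± 0.21 SE, 4 arrays against 4). AT5G48570 rose by 2.17 ± 0.23, AT3G28270 by 1.87 ± 0.34, HYH by 1.82 ± 0.16, AT1G68440 by 1.80 ± 0.32, AT3G56290 by 1.79 ± 0.16, AT1G66100 by 1.77 ± 0.29 and AT5G12110 by 1.76 ± 0.17. AT2G30600 fell 4.16-fold (-2.06 ± 0.20), followed by AT5G27280 (-1.93 ± 0.38), CCL (-1.79 ± 0.16), AT3G51660 (-1.78 ± 0.17), AT1G56300 (-1.70 ± 0.19), AT1G70820 (-1.68 ± 0.15), AT5G47455 (-1.60 ± 0.30) and AT2G28720 (-1.45 ± 0.23). At 48 h 3262 probe sets passed, 1531 up and 1731 down, and at least 2-fold changes numbered 144 up and 107 down. GI was at -0.24 ± 0.16 and did not pass.

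Histones, mitosis, replication and ribosomal protein genes were lower at 48 h than at 2 h. Of 11 histones 10 fell, with AT1G06760 at -0.90 ± 0.09 and AT2G37470 at -0.93 ± 0.14 (list adjusted p = 1.10e-08, adjusted p = 0.103 with an estimated correlation). Of 17 mitosis genes 8 fell, with 3xHMG-box2 at -1.03 ± 0.15 and the checkpoint gene BUBR1 at -0.70 ± 0.14 (list adjusted p = 1.31e-04, adjusted p = 0.141 with an estimated correlation). Of 12 replication genes 6 fell, with CHR17 at -0.73 ± 0.13 and ASF1B at -0.71 ± 0.14 (list adjusted p = 8.90e-04, adjusted p = 0.289 with an estimated correlation). Of 119 ribosomal protein genes 36 fell, with a median of -0.16, which was -0.26 under quantile normalization, and AT1G23410 at -1.01 ± 0.14 (list adjusted p = 1.51e-07, adjusted p = 0.450 with an estimated correlation). Nuclear photosynthesis genes rose as a list, 9 of 22, with NdhL at 0.67 ± 0.13 and NdhN at 0.59 ± 0.12, both of the NDH complex (list adjusted p = 1.53e-04, adjusted p = 0.450 with an estimated correlation). Of 42 plastid-encoded photosynthesis genes 3 rose, psbD (0.59 ± 0.21), ndhG (0.51 ± 0.18) and ndhI (0.40 ± 0.14), with 0.00130 for the list and an adjusted p of 0.623 with an estimated correlation. Of 19 plastid polymerase and ribosome genes rpoA (0.46 ± 0.14) and rps2 (0.41 ± 0.13) rose, with 0.0236 for the list and an adjusted p of 0.618 with an estimated correlation. Of 17 UGT glycosyltransferases 6 rose, with UGT78D1 at 0.76 ± 0.12 and UGT71B1 at 0.68 ± 0.13 (list adjusted p = 0.0224, adjusted p = 0.244 with an estimated correlation). Of 7 SWEET sugar transporters SWEET2 (0.76 ± 0.12), SWEET1 (0.75 ± 0.10) and SWEET11 (0.61 ± 0.17) rose (list adjusted p = 0.0386, adjusted p = 0.178 with an estimated correlation). The calls were lost without developing 2 h replicate 3 for the plastid polymerase list (0.0782) and the UGT list (0.0720), and without developing 2 h replicate 4 for the SWEET list (0.0912). Without the filter the UGT list (0.235) and the SWEET list (0.145) did not pass either, the SWEET list was also lost with a pseudocount of 21.7 (0.0673) and the filter at the 60th percentile (0.0805), and the plastid polymerase list was lost with the actin ratio as a covariate (0.154) and the filter at the 60th percentile (0.0590). psbD, ndhG, ndhI, rps2 and rpoA did not pass without 7, 6, 4, 4 and 2 of the 8 arrays left out in turn, with an adjusted p of up to 0.151, 0.155, 0.135, 0.0800 and 0.0643. Without the filter psbD (0.0783), ndhG (0.0756) and ndhI (0.0697) did not pass, and psbD and ndhG lost their calls with the replicate block too (adjusted p of up to 0.0521) and psbD without the variance trend (0.0531), as did ndhI (0.167) and rps2 (0.181) with the actin ratio as a covariate. The actin control ratio was 2.66 ± 0.15 (SD, n = 4) at 2 h and 2.00 ± 0.50 at 48 h (exact permutation p = 0.0571, 0.229 adjusted over 24 tests), and 2775 probe sets passed with it as a covariate.

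By 96 h, AT3G60420 had risen 10.2-fold over 2 h (log2 3.35 ± 0.43 SE, 4 arrays against 4) and AT3G16530 9.19-fold (3.2 ± 0.40). AT5G52760 rose by 2.78 ± 0.32, AT5G48570 by 2.7 ± 0.23, AT5G24210 by 2.60 ± 0.37, RING1, a RING-type ubiquitin ligase, by 2.39 ± 0.25, AT3G56290 by 2.35 ± 0.16 and AT5G44580 by 2.34 ± 0.19. AT5G47455 fell 5.84-fold (-2.55 ± 0.30), followed by AT2G30600 (-2.38 ± 0.20) and GH3.3, which conjugates auxin to amino acids (-2.11 ± 0.27). AT1G23100 (-2.06 ± 0.21), AT1G29270 (-2.05 ± 0.19), AT4G17470 (-2.03 ± 0.53), AT4G17610 (-2.01 ± 0.29) and AT4G30650 (-2.01 ± 0.18) fell as well. Of 13648 probe sets 5708 passed, 2611 up and 3097 down, and at least 2-fold changes numbered 431 up and 343 down. The count was 4208 with the actin and 4884 with the ubiquitin ratio as a covariate, and AT4G17470 did not pass with the latter (-1.31, adjusted p = 0.143). GI was at 0.07 ± 0.16 and did not pass.

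Ribosomal protein genes and genes of cell division were lower at 96 h than at 2 h. Of 119 ribosomal protein genes 77 fell and none rose, with a median of -0.33, AT1G23410 at -1.54 ± 0.14 and AT4G30800 at -1.18 ± 0.11 (list adjusted p = 4.80e-12, adjusted p = 0.319 with an estimated correlation). Of 17 mitosis genes 14 fell, with 3xHMG-box2 at -1.30 ± 0.15 and BUB3.1 at -1.15 ± 0.12 (list adjusted p = 5.05e-05, adjusted p = 0.141 with an estimated correlation). Of 11 histones 10 fell, with AT2G37470 at -1.46 ± 0.14 and the histone H2B gene HTB1 at -1.22 ± 0.12 (list adjusted p = 2.40e-07, adjusted p = 0.141 with an estimated correlation). Of 12 replication genes 9 fell, with ASF1B at -1.0 ± 0.14 and PRL at -0.85 ± 0.11 (list adjusted p = 5.87e-04, adjusted p = 0.275 with an estimated correlation). Of 22 nuclear photosynthesis genes 14 rose and 1 fell, with LHCB4.3 at 0.87 ± 0.14, NdhL at 0.86 ± 0.13 and SBPASE at 0.70 ± 0.11 (list adjusted p = 3.25e-04, adjusted p = 0.462 with an estimated correlation). Their median was 0.40, with 0.24 under quantile normalization, 0.26 with the actin ratio and 0.60 with the ubiquitin ratio as a covariate. Of 42 plastid-encoded photosynthesis genes 8 rose, with psbD at 0.78 ± 0.21 and ndhK at 0.78 ± 0.21 (list adjusted p = 0.0469, adjusted p = 0.745 with an estimated correlation). Of 17 UGT genes 7 rose, with UGT87A2 at 1.73 ± 0.13 and UGT78D2 at 0.81 ± 0.16 (list adjusted p = 0.0231, adjusted p = 0.244 with an estimated correlation). The actin control ratio moved along with these groups, from 2.66 ± 0.15 (SD, n = 4) at 2 h to 1.53 ± 0.50 at 96 h, and the ubiquitin ratio from 1.64 ± 0.24 to 1.17 ± 0.14. Both had an exact permutation p of 0.0286, the smallest possible, and 0.229 adjusted over 24 tests. The values at 2 h and at 96 h did not overlap in either ratio. The plastid list was lost with the actin ratio as a covariate (adjusted p = 0.270), under quantile normalization (0.189), without the filter (0.0699), without the variance trend (0.0538), and without developing 2 h replicate 3 or 4 (0.133 and 0.0710) or developing 96 h replicate 2 or 3 (0.169 and 0.0888). The UGT list was lost without developing 2 h replicate 3 (0.0613) and under both other filters (0.0561 and 0.0754).

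**Figure D2:**
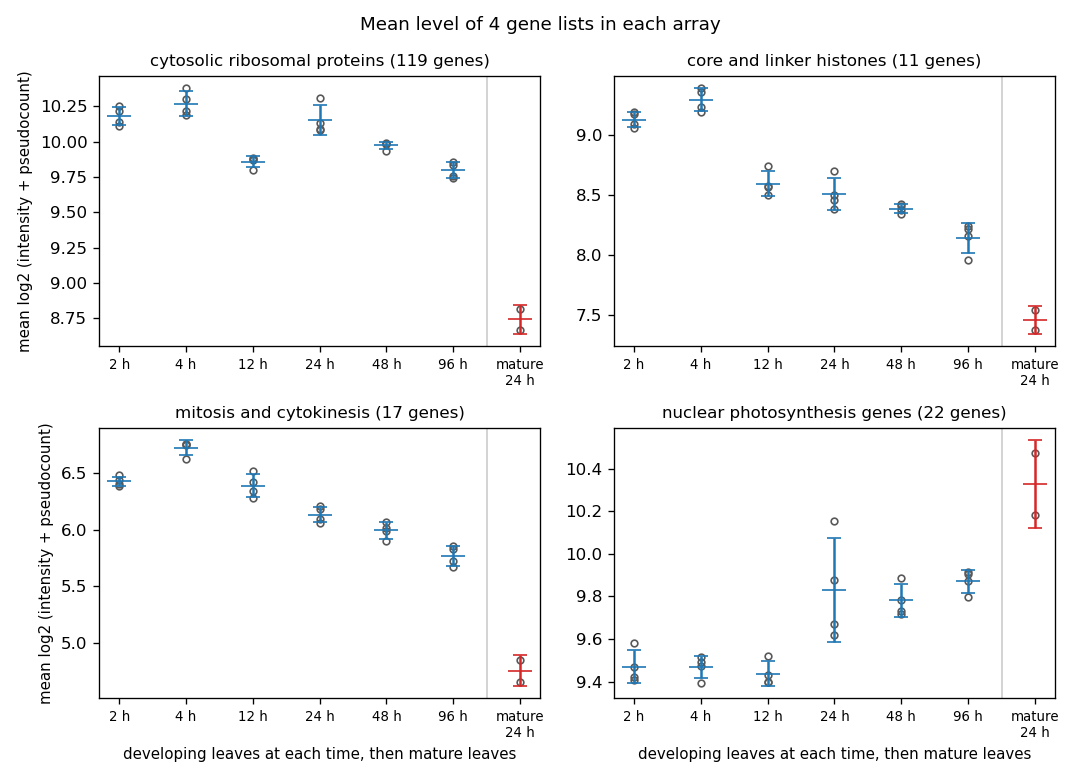
Mean log2 intensity plus pseudocount over the measured genes of 4 lists in each array (circles), with the group mean and SD (bars), for developing leaves at 6 times (blue) and mature leaves at 24 h (red). The mean of the 17 mitosis genes was at 6.72 at 4 h, 5.77 at 96 h and 4.76 in mature leaves, and that of the 119 ribosomal protein genes was at 10.18 at 2 h, 9.80 at 96 h and 8.74 in mature leaves.

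From 24 h to 48 h, a whole day apart, few genes passed and their changes were small. AT1G68600 rose 2.00-fold (log2 1.00 ± 0.22 SE, 4 arrays against 4), TBL26 by 0.93 ± 0.21, the plastid gene petG, for a subunit of the cytochrome b6f complex, by 0.89 ± 0.18, AT1G73600 by 0.88 ± 0.14 and AT1G19960 by 0.85 ± 0.16. AT3G56080 rose by 0.79 ± 0.17, AT2G40435 by 0.69 ± 0.14 and UGT76E11 by 0.65 ± 0.13. AT5G26680 fell by 0.71 ± 0.13, the homocysteine methyltransferase gene HMT-1 by 0.44 ± 0.10 and the ribosomal protein genes AT5G52650 and AT3G09200 by 0.42 ± 0.09 each. AT4G14420, AT1G73230, AT3G63400 and AT3G14100 fell by 0.40 ± 0.09, 0.39 ± 0.08, 0.38 ± 0.08 and 0.35 ± 0.07. Only 43 of 13648 probe sets passed, 24 up and 19 down, and 1908 had an unadjusted p under 0.05. In limma none passed without developing 24 h replicate 1 (1911 at an unadjusted p under 0.05) or developing 48 h replicate 3 (1551), and 1 passed with the arrays of these groups only (1578). Without developing 48 h replicates 1 and 4 and developing 24 h replicates 2 and 3, each left out alone, 18, 4, 104 and 12 passed, and every gene named here lost its call without 2 or more of the 8 arrays. The ubiquitin control ratio was 1.71 ± 0.11 (SD, n = 4) at 24 h and 1.54 ± 0.10 at 48 h (exact permutation p = 0.0857, 0.229 adjusted over 24 tests), and 16 probe sets passed with it as a covariate and 95 with the actin ratio.

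As lists, cytosolic ribosomal proteins had a median log2 fold of -0.21 from 24 h to 48 h, with 2 of 119 members down over all probe sets and 57 when adjusted over the list alone. The list had an adjusted p of 1.73e-20 and an adjusted p of 0.187 with an estimated correlation, and its median was -0.09 under quantile normalization. Of 17 UGT genes UGT76E11 rose, with 5.86e-04 for the list, an adjusted p of 0.141 with an estimated correlation, and 0.213 without the filter. Among 42 plastid-encoded photosynthesis genes petG rose, while atpB was at -0.50 ± 0.15 (adjusted p = 0.138), and the list had a median of 0.25, which was 0.04 without developing 24 h replicate 2, 0.16 without developing 48 h replicate 2 and 0.38 with array weights. The plastid photosynthesis list had an adjusted p of 0.00138 and an adjusted p of 0.623 with an estimated correlation, and the 19 plastid polymerase and ribosome genes, none called, had 0.00990 and an adjusted p of 0.593 with an estimated correlation. Without developing 24 h replicate 2 neither plastid list passed (adjusted p = 0.943 and 0.489). No member was called among 7 CYP71 cytochromes P450 (median 0.32, list adjusted p = 0.0139, adjusted p = 0.141 with an estimated correlation), 5 tetraspanins (0.23, 0.0310, adjusted p = 0.170 with an estimated correlation) and 17 mitosis genes (list adjusted p = 0.0462, adjusted p = 0.405 with an estimated correlation). The tetraspanin call was lost without developing 24 h replicate 2 or 4 (adjusted p = 0.0584 and 0.0596) or developing 48 h replicate 1 or 2 (0.0602 and 0.0655), and with array weights (0.0666). It was also lost with the filter at the 60th percentile, where the median was 0.04, and without the filter, where the median turned to -0.02. The mitosis call was lost without developing 24 h replicate 2, 3 or 4 (0.148, 0.0928 and 0.0555) or developing 48 h replicate 1 or 2 (0.0892 and 0.195), and under 4 other settings.

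Over the 3 days from 24 h to 96 h, AT3G60420 rose 8.70-fold (log2 3.1 ± 0.43 SE, 4 arrays against 4). AT5G52760 rose by 2.71 ± 0.32, RING1 by 2.37 ± 0.25, AT5G24210 by 2.29 ± 0.37, AT2G18690 by 2.28 ± 0.32 and the chitinase gene annotated as CHI by 2.25 ± 0.44. AT3G47480 rose by 1.99 ± 0.35 and AT5G12940 by 1.65 ± 0.28. AT4G17470 fell 3.62-fold (-1.86 ± 0.53), followed by AT4G17860 (-1.52 ± 0.28), GH3.3 (-1.2 ± 0.27), AT1G29270 (-1.19 ± 0.19), AT5G15510 (-1.1 ± 0.21) and AT5G44500 (-1.02 ± 0.21). GLC fell in both of its probe sets (-1.06 ± 0.13 and -1.04 ± 0.15). Of 13648 probe sets 2354 passed, 1147 up and 1207 down, and at least 2-fold changes numbered 161 up and 17 down. The count was 1378 with the arrays of these groups only and 1259 with the ubiquitin ratio as a covariate, and AT4G17470 did not pass without developing 24 h replicate 1 or developing 96 h replicate 4 (adjusted p of up to 0.0701), with array weights (0.0549) or with the ubiquitin ratio as a covariate (-1.04, 0.421).

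Ribosomal protein genes fell broadly from 24 h to 96 h, 93 of 119 with a median of -0.36. AT3G13580 fell by 0.55 ± 0.10 and AT4G13170 by 0.52 ± 0.08 (list adjusted p = 4.55e-29, adjusted p = 0.141 with an estimated correlation), and the median was -0.23 under quantile normalization. Of 11 histones 8 fell, with HTB2 at -0.83 ± 0.20 and AT1G09200 at -0.61 ± 0.11 (list adjusted p = 2.13e-04, adjusted p = 0.177 with an estimated correlation). Of 17 mitosis genes 8 fell, with BUBR1 at -0.77 ± 0.14 and AUR3 at -0.64 ± 0.13 (list adjusted p = 3.25e-04, adjusted p = 0.168 with an estimated correlation). Of 12 replication genes 6 fell, with PRL at -0.59 ± 0.11 and ASF1B at -0.54 ± 0.14 (list adjusted p = 0.00415, adjusted p = 0.352 with an estimated correlation). Of 17 UGT genes 4 rose, with UGT87A2 at 1.42 ± 0.13 and UGT71C4 at 0.42 ± 0.11 (list adjusted p = 9.37e-04, adjusted p = 0.141 with an estimated correlation). Of 5 tetraspanins TET3 (1.05 ± 0.14), TET2 (0.99 ± 0.15) and TET8 (0.73 ± 0.13) rose, with 0.0224 for the list and an adjusted p of 0.159 with an estimated correlation. The tetraspanin list had a median of 0.73, and its call was lost without the filter (median 0.02, adjusted p = 0.242) and with the filter at the 60th percentile, where the median turned to -0.08 (0.724). The ubiquitin control ratio moved along with these groups, from 1.71 ± 0.11 (SD, n = 4) at 24 h to 1.17 ± 0.14 at 96 h, with an exact permutation p of 0.0286 and 0.229 adjusted over 24 tests. With that ratio as a covariate HTB2 (-0.66, adjusted p = 0.150) and ASF1B (-0.20, 0.538) did not pass.

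Mature leaves differed from developing leaves at 24 h in most measured transcripts. AT1G64370 was 33.1-fold higher in mature leaves (log2 5.05 ± 0.39 SE, 2 arrays against 4), CHI 30.1-fold (4.91 ± 0.54) and the metallothionein gene MT1C 25.8-fold (4.69 ± 0.39). BCAT4, of methionine chain elongation in glucosinolate synthesis, was higher by 4.60 ± 0.32 and the zinc finger gene STZ by 4.27 ± 0.25. AT5G24210 (4.61 ± 0.45), AT2G25450 (4.50 ± 0.31), AT1G67860 (4.41 ± 0.46), RING1 (4.40 ± 0.30), AT1G67865 (4.40 ± 0.28), AT1G67870 (4.28 ± 0.37) and AT3G60420 (4.25 ± 0.53) were higher as well. Among named genes the largest decrease was that of AT2G33850 (-7.53 ± 0.19), followed by AT5G62210 (-5.50 ± 0.24), AT5G33370 (-4.98 ± 0.18), AT4G29030 (-4.85 ± 0.27), AT5G45670 (-4.76 ± 0.15), AT1G62500 (-4.45 ± 0.33), AT5G48490 (-4.42 ± 0.15) and AT5G48360 (-4.21 ± 0.19). LCR69 (-4.0 ± 0.14), SPCH, which starts the stomatal lineage (-3.99 ± 0.25), AT3G12870 (-3.93 ± 0.20) and AT4G29020 (-3.92 ± 0.13) were lower too. AT2G33850, AT5G62210, AT5G48360, SPCH and AT3G12870 were near the floor in mature leaves, at 2.76 to 3.44, where the pseudocount sets the size of a fold. Of 13648 probe sets 8423 passed, 3290 up and 5133 down, with 1321 and 1950 at 2-fold or more, and the median over all probe sets was -0.15. With 2 mature arrays no split of the arrays was tested.

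Transcripts of protein synthesis and cell division were lower in mature than in developing leaves. Of 119 ribosomal protein genes 115 were lower and none higher, with a median of -1.37, AT3G52580 at -2.23 ± 0.09 and AT3G10610 at -2.10 ± 0.11 (list adjusted p = 2.17e-28, adjusted p = 0.141 with an estimated correlation). Of 17 mitosis genes 15 were lower and 1 higher, with TOPII, near the floor in mature leaves, at -3.74 ± 0.22 and 3xHMG-box2 at -3.27 ± 0.18 (list adjusted p = 5.61e-04, adjusted p = 0.171 with an estimated correlation). Of 12 replication genes 10 were lower, with PRL at -2.40 ± 0.13 and ICU2, a DNA polymerase alpha subunit, at -1.90 ± 0.17 (list adjusted p = 5.87e-04, adjusted p = 0.275 with an estimated correlation). Of 11 histones 8 were lower and 1 higher, with AT1G09200 at -2.55 ± 0.13 and HTB1 at -2.34 ± 0.14. The histone list had an adjusted p of 0.0351, an adjusted p of 0.422 with an estimated correlation, and 0.0603 with the arrays of these groups only. Of 10 IQD calmodulin-binding proteins 7 were lower, with IQD26 at -1.98 ± 0.23 and iqd21 at -1.48 ± 0.11 (list adjusted p = 0.0262, adjusted p = 0.244 with an estimated correlation). The actin control ratio was 1.60 ± 0.56 (SD, n = 2) in mature and 2.14 ± 0.49 (n = 4) in developing leaves (exact permutation p = 0.267), and the ubiquitin ratio 1.28 ± 0.34 and 1.71 ± 0.11 (exact permutation p = 0.0667, the smallest possible).

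Photosynthesis and ageing genes were higher in mature leaves. Of 8 genes of senescence and organ ageing 7 were higher, with the vacuolar processing enzyme gene GAMMA-VPE at 2.18 ± 0.22 and the autophagy gene ATG8F at 1.74 ± 0.15 (list adjusted p = 0.00130, adjusted p = 0.168 with an estimated correlation). Of 22 nuclear photosynthesis genes 15 were higher and 2 lower, with NdhL at 1.47 ± 0.16 and NdhS at 1.38 ± 0.19 (list adjusted p = 0.00242, adjusted p = 0.509 with an estimated correlation). Their median was 0.49, with 0.23 under quantile normalization, 0.75 without mature 24 h replicate 1 and 0.27 without mature 24 h replicate 2. Of 42 plastid-encoded photosynthesis genes 18 were higher, with psbA, for the D1 protein of photosystem II, at 1.87 ± 0.33 and psbE at 1.36 ± 0.19 (list adjusted p = 0.00130, adjusted p = 0.623 with an estimated correlation). The median of the plastid list was 0.46, and 0.85 without mature replicate 1, 0.28 without developing 24 h replicate 2 and 0.10 without mature replicate 2, where the list did not pass (adjusted p = 0.218). Of 7 CYP71 genes 4 were higher and 1 lower, with CYP71B26 at 2.40 ± 0.16 and CYP71B24 at 2.33 ± 0.20 (list adjusted p = 0.0278, adjusted p = 0.170 with an estimated correlation). With the filter at the 60th percentile the CYP71 list (0.0690) and the IQD list (0.0674) did not pass.

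The lists fixed in advance held few measured genes, and none of the 9 that were tested passed, the lowest adjusted p being 0.0603. In mature leaves all 3 glucosinolate synthesis genes were higher (3 adjusted over the list alone, median 1.72, list adjusted p = 0.0603), with BCAT4 at 4.60 and UGT74B1 at 1.2. Of 3 stomatal lineage genes 2 were lower (2 adjusted over the list alone), SPCH and STOMAGEN (-1.97), and the list had an adjusted p of 0.143. All 4 Calvin cycle enzymes (4 adjusted over the list alone, 0.143), all 3 light-harvesting proteins (3, 0.248), 2 of 4 photosystem subunits (3, 0.292) and 3 of 4 carbon starvation genes (3, 0.292) were higher. Of 4 expansins and xyloglucan enzymes 3 were lower and EXPA8 higher, of 3 leaf growth regulators YAB3 and PHV were lower (2 adjusted over the list alone), and of 3 flavonoid genes 1 was lower (0 adjusted over the list alone), with list adjusted p of 0.496, 0.292 and 0.916. Lists with 1 or 2 measured genes gave single values in mature leaves. AUR1 (-1.88) and AUR2 (-1.72) of the cell cycle, PRL and ICU2 of replication and the nucleolar genes AT3G05060 (-1.92) and AT5G14520 (-1.97) were lower. APL3 (1.5) and SBE2.2 (0.90) of starch synthesis, GH3.3 (0.97) and WES1 (1.21) of auxin response, STZ of the touch response and TRY (0.98), the only measured trichome marker, were higher. DPE1 of starch breakdown (-0.36), HYH of light signalling (-0.67) and AT5G48570 of the heat shock list (-1.06) were lower, while PWD (-0.16) and ATHSP22.0 (-0.19) did not pass. No gene was measured for nitrogen assimilation, chlorophyll breakdown, salicylic acid, jasmonate, or the markers of meristem, flower, guard cells, phloem and xylem, so the share of other cell types in the leaves was not tested beyond TRY.

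Of the 34 added lists that were tested, 17 passed in at least 1 comparison, in 53 of 272 tests, and the other 17 passed in none. Nearest to the threshold among these, both in mature leaves, were 12 genes of leaf shape and margin, 7 lower and 1 higher (adjusted p = 0.0820), and 7 tubulins, 6 lower and 1 higher (0.0836), with TUB7, chosen after its value was seen, at -2.69. The other lists without a pass were subtilases, ubiquitin-conjugating enzymes, ubiquitin proteases, ubiquitin ligases, glutathione transferases, RALF-like peptides, TBL proteins, endoglucanases, MADS-box factors, bZIP factors, TRM proteins, beta-glucosidases, glutamate receptor-like channels, NET proteins and clock-associated genes, with lowest adjusted p between 0.0955 and 0.493.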

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

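The test of the control ratios on developing 24 h replicate 1 was chosen after the array had been seen, and its bound was loosened once the ratios were known. The other tests in this part were planned before their results, but reading the test of the group label against the other arrays of the group was added afterwards.

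Developing 24 h replicate 1 stood apart from the other 3 arrays of its group: its deviation from their mean had an SD of 0.374 across probe sets, against at most 0.296 in any other developing array, and 199 probe sets lay more than 1 log2 unit away. A wrong group label cannot be told apart from other causes, since this array correlated better with the 48 h arrays than with its own by 0.00241, but the other arrays of its group did so as well, by 0.00144 to 0.00483. RNA integrity stays open too, because 1 of its 3 control ratios, that of GAPDH (0.962 against 0.039 to 0.416), was the highest of the group, while the actin ratio was the lowest (1.71 against 1.73 to 2.60). Admixture of older leaf tissue also stays open, as the deviation correlated with the difference between mature and 48 h leaves at r = 0.205 across probe sets, inside the range of -0.24 to 0.28 over the other developing arrays. No biological explanation was tested.

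In 18 of 258 groups tested, over 43 measures, the highest or the lowest array lay far from the other 3, with a gap above the critical share of the group's range. Chance alone gives about 1 in 20. In developing 24 h replicate 1, glucosinolate synthesis genes were high, with a mean of 7.37 against 6.90 to 6.98 (gap 0.832 of the range), and so was AT5G12110, 10.10 against 9.35 to 9.46 (0.862). In developing 24 h replicate 2, plastid-encoded photosynthesis genes were low, with a mean of 8.98 against 9.72 to 9.86 (0.838). Senescence and ageing genes were high in developing 2 h replicate 1, 6.70 against 6.44 to 6.47 (0.881), and in developing 48 h replicate 1, 6.85 against 6.48 to 6.49 (0.970). The mean correlation with the group was also low in developing 2 h replicate 1, 0.979 against 0.981 (0.869), and the median intensity was high in developing 48 h replicate 1, 46.4 against 42.0 (0.993). In developing 12 h replicate 2, ribosomal protein genes were low, 9.80 against 9.87 to 9.88 (0.876), as were stomatal lineage genes, 6.51 against 6.87 to 6.92 (0.882). In developing 48 h replicate 4, AT5G52660 was low, 5.61 against 5.95 to 5.98 (0.923), as were BGLU40, 8.39 against 8.54 to 8.55 (0.912), and SWEET sugar transporters, 6.85 against 6.94 to 6.95 (0.878). Expansins were low in developing 2 h replicate 2, 6.32 against 6.53 to 6.54 (0.935), and mitosis genes in developing 4 h replicate 2, 6.63 against 6.75 to 6.76 (0.905). AT4G32340 was high in developing 4 h replicate 4, 7.46 against 6.83 to 6.93 (0.837). At 96 h, the actin ratio was high in replicate 1, 2.28 against 1.22 to 1.31 (0.912), AT5G12110 was low in replicate 3, 8.99 against 9.48 to 9.55 (0.885), and Calvin cycle enzymes were low in replicate 4, 10.79 against 10.92 to 10.94 (0.862).

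Other splits of the arrays into groups of the same sizes tested whether chance gives as many probe sets. For the F-test, 1 of 100 splits, the real one, gave as many as the real 8677, and the highest other gave 571. In each contrast against 2 h, 1 of 35 splits, the real one, gave as many, and the real counts and the highest others were 356 and 1 at 4 h, 5560 and 1 at 12 h, 2028 and 1 at 24 h, 3726 and 5 at 48 h and 5888 and 0 at 96 h. For 96 h against 24 h it was again 1 of 35, with 1378 and 0. No other split that was tried thus gave as many calls in these. With 35 splits, 1 of 35 is the lowest share possible, and it was not adjusted over the contrasts. Nor can the splits tell time from anything else that the arrays of 1 time shared. For 48 h against 24 h, 5 of 35 splits gave at least the real count of 1, the highest other giving 2, and chance is not excluded. These fits used the arrays of the compared groups only, and neither the fits nor the splits took account of the replicate number.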

How the results depend on the processing

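Developing 24 h replicate 1 out of the fit, array weights and the ratios of actin and ubiquitin as covariates were chosen after seeing the data, and the other alternatives before. The counts of probe sets stayed within 1.5 times their reported values under each alternative, except in 3 comparisons, and the cause of these was not tested beyond what the settings state. For 48 h against 24 h the count of 43 became 28 without the filter, 21 without the variance trend, 1 with the arrays of the compared groups only, 171 with array weights, 95 with the actin ratio, 16 with the ubiquitin ratio, and 0 with developing 24 h replicate 1 out of the fit, where limma gave 1911 probe sets at an unadjusted p under 0.05. For 96 h against 24 h the count of 2354 became 1378 with the arrays of these groups only and 1259 with the ubiquitin ratio. Fitting the compared groups only leaves fewer residual degrees of freedom in every comparison. Yet under it the counts at 4, 12, 48 and 96 h against 2 h rose, to 356, 5560, 3726 and 5888. Counts fell in the time comparisons that hold developing 24 h, with 2856 becoming 2028 at 24 h against 2 h. For 4 h against 2 h the count of 319 became 567 with array weights. Leaving out 1 array at a time gave 0 to 104 for 48 h against 24 h, 1571 to 2315 for 96 h against 24 h, 223 to 315 at 4 h, 4599 to 5048 at 12 h, 2051 to 2825 at 24 h, 2585 to 3163 at 48 h and 5020 to 5368 at 96 h against 2 h, 8053 to 8602 for the F-test and 7296 to 8505 for mature leaves, with the lone mature array assumed to vary like the other groups. LHCB4.1 turned from 0.59 to -0.031 at 24 h against 2 h under quantile normalization, and the cause was not tested. Of 365 values of named genes, 339 kept their side of the threshold with the arrays of the compared groups only, the lowest number. The number was 345 with the ubiquitin ratio and 345 with developing 24 h replicate 1 out of the fit. It was 349 with array weights, 350 without the filter and 359 under quantile normalization. Of 125 list values, 104 kept their side without the filter, 78 of 93 with the filter at the 60th percentile, and 121 under quantile normalization. Values past the threshold also had to keep their direction to be counted. Direction was not compared for the F-test or for values that did not pass, and for lists it was that of camera, not of the median. The labels do not say that the replicate numbers mark pairs, and the main fit did not use them so. Across developing arrays, deviations from the group mean correlated with a mean r of 0.082 between arrays of the same number and of -0.027 between others. The second value follows largely from the first, since the deviations cancel within a group. An r above 0.1 was reached by 23 of 60 pairs of the same number and by 27 of 180 others. Of 24 arrays 16 correlated best with their own number, with 4 numbers to choose from. The main fit may thus leave out a shared effect of the number. With the number as a block the counts were 8715 for the F-test, 376, 5525, 3062, 3493 and 5887 at 4, 12, 24, 48 and 96 h against 2 h, 64 for 48 h and 2570 for 96 h against 24 h, and 8313 for mature leaves. The mature arrays entered that block with developing replicates 1 and 2, although the labels set their numbers apart with an added m. Without detection calls, signal over background was not known for single probe sets.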

Other observations

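The tests of the GAPDH ratio, of leaf ageing, of the covariance across splits and with the control ratios as covariates, and of the daily cycle were chosen after the result they measure had been seen, and the others before, except that the ranges over arrays at 4 h and 12 h were added afterwards.

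Genes for starch breakdown, 2 of which were measured, moved opposite to HYH, a pairing chosen after the values were seen. DPE1 rose by 0.70 at 4 h and by 1.03 at 12 h against 2 h, and was at -0.79 at 24 h, -0.83 at 48 h and -0.97 at 96 h, all past the threshold. PWD rose by 0.62 at 4 h and by 1.27 at 12 h and was at -0.31 at 24 h and -0.25 at 96 h, which passed, and at -0.16 at 48 h, which did not. HYH was at -0.85, -0.65, 1.55, 1.82 and 1.86 at these times, all past the threshold. Of the probe sets called at 96 h against 2 h, 1612 that rose were also higher and 2312 that fell were also lower in mature leaves. Fewer moved the opposite way, as 308 that rose were lower and 186 that fell were higher in mature leaves. Examples, chosen after their values were seen, are that GH3.3 was at -2.11 at 96 h against 2 h and at 0.97 in mature leaves, and AT5G48570 at 2.7 and -1.06.

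A hypothesis is that part of the change over 4 days was leaf ageing, since log2 folds from 2 h to 96 h in developing leaves ran with those from developing to mature leaves, with r = 0.560 across probe sets, which are not independent replicates, and no array in common. At 4, 12 and 48 h the r was -0.04, 0.26 and 0.41. At 96 h and in mature leaves alike, 1612 probe sets were higher and 2312 lower, against 629 and 1165 if the calls were independent. But the mean of the 8 senescence and organ ageing genes was 6.52 ± 0.12 (SD, n = 4) at 2 h and 6.56 ± 0.07 at 96 h, against 7.60 in mature leaves. Replicate 1 raised the 2 h mean, at 6.70 against 6.44 to 6.47 in the other arrays. The list did not pass at 96 h (camera adjusted p = 0.545). Chance is not excluded by r, which ignores size. Of 35 splits of the 2 h and 96 h arrays 4 gave an r as strong, the highest other at 0.596. By covariance 1 of 35, the real one, was as strong (0.281, the highest other 0.181). The covariance grows with the size of the folds, which mixing the 2 h and 96 h arrays shrinks, so it cannot decide on chance. The actin ratio was 2.66 at 2 h and 1.53 at 96 h, and the ubiquitin ratio 1.64 and 1.17. Each was entered as a covariate in the 96 h folds, fitted without the 24 h arrays. The calls went from 6160 to 3984 and 4984. The covariance was 0.289 and 0.336, at least 0.212 and 0.318 with any 1 array left out. With these arrays the covariance was thus not lower than without a covariate (0.281). That cannot decide on RNA integrity as the whole cause. The slopes rest on differences between arrays of the same time, where noise in a ratio weakens the correction. These ratios are an uncertain measure of RNA integrity, since at 96 h replicate 1 had the highest actin (2.28) and the lowest GAPDH ratio (0.071). RNA integrity therefore stays open, as a part or the whole of the cause and beyond what these ratios measure. The GAPDH ratio gave an exact permutation p of 0.114. With the covariate in both folds r was 0.550 for actin, under the highest other split, and 0.616 for ubiquitin, above it. Leaf ageing may contribute but is left open by the senescence list and has no second age of mature leaves to test it.

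A second hypothesis is that the daily cycle, in which 24, 48 and 96 h lie 2 h earlier than 2 h, accounts for part of the change. Most probe sets that changed from 2 h to 4 h lay on the opposite side of their 2 h level at 24, 48 and 96 h. Of the 319, this held by sign for 259 at 24 h (81.2%, the lowest of the 3 times), 279 at 48 h and 270 at 96 h. Past the threshold against 2 h were 179, 208 and 229 in the opposite direction and 10, 10 and 21 in the same direction. The 2 h arrays that these folds share push them the same way, not apart. For the 319 as a set, a response to the start of the experiment that was already fading at 12 h is argued against. Along the 2 h to 4 h direction their median at 12 h lay 1.19 from the 24 h level and at 4 h 1.06. The ranges over arrays, 1.13 to 1.19 and 0.96 to 1.07, did not overlap. Single genes differed, as GI had fallen below its 2 h level by 12 h while CCL and AT4G32340 had gone on rising. The share of the 319 that had turned back by 12 h was not counted. A response that peaked near 12 h and ended by 24 h may still account for the pattern, as may the daily cycle, since no later group was taken at the phase of 2 h to tell phase from elapsed time.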
